A study of Rattus norvegicus with 69 samples.

How the data were processed

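Gene expression was measured on 69 one-colour Affymetrix Rat Genome 230 2.0 arrays, 1 per tissue sample. Of these, 49 held urinary bladder and 20 held non-glandular stomach, all from female Sprague Dawley rats. The rats were given vehicle or 100 mg/kg of a compound named only as C1 by daily oral gavage. Per the labels, total RNA was reverse transcribed and biotin-labelled cRNA was hybridized. The deposited values are intensity on a linear scale for 31099 probe sets. They had been corrected for background by the authors, as values below 0 show (10.1% to 12.5% of the values of an array), and had not been brought to a common scale between arrays. The sources used here do not give the summary method of the deposited values, so it is not known which algorithm combined the probes of a set. Of the probe sets, 57 are array controls, 20826 carry 1 gene symbol, 436 several and 9780 none. Entrez numbers placed 20764 of the 20826 in the RefSeq gene table for rat, and 0 symbols changed. The 20826 stand for 14217 genes, 4525 of them with more than 1 probe set, and the probe set with the highest mean over the 69 arrays stood for its gene.

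Array means ran from 649.8 to 1501 intensity units in the bladder and from 298.1 to 538.9 in the stomach. The arrays were therefore quantile normalized within each tissue before any comparison was tested. This departs from the choice made before the data were examined, which was to use the values as deposited; that choice is given among the alternatives. The common distribution of each tissue was then given a lower bound, called the floor, at the size of its percentile 1 (146.8 intensity units or log2 7.20 in the bladder, 28.25 or log2 4.82 in the stomach), and log2 was taken. A gene was tested where at least 4 arrays of its tissue lay above the floor, which left 11277 genes in the bladder, 11633 in the stomach and 10916 in both. On each array 72.6% to 78.2% of the genes lay above the floor. The number of arrays and the floor limit the precision, since a gene at the floor on all arrays of a group has a change known only as a bound.

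limma 3.58.1 in R 4.3.3 fitted 1 mean per group of tissue, treatment and time, with all arrays of a tissue sharing 1 estimate of the spread. limma's moderated test, two-sided, was read for C1 against vehicle at each time, for differences of these effects between neighbouring times and between tissues, and as an F-test for change over time. Benjamini-Hochberg adjustment ran over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Gene lists (48 lists, 997 genes named, 893 found on the array) were fixed before the data were examined. They were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes, adjusted over all 312 tests of lists with at least 5 measured members. Camera with a correlation estimated per list and limma's fry were run beside it. Members of a list are counted as called over all genes tested and as called when adjusted over the list alone. Array controls and RNA quality were compared with exact permutation tests, two-sided. Errors written with ± are standard errors from limma on the log2 scale unless SD is stated. Groups hold 5 arrays, except C1 in the bladder at 48 h with 4.

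Named genes followed a rule set before the data were examined. Per comparison of C1 with vehicle, these were the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap and whose higher group mean exceeds percentile 25 of all genes. The rule added the 8 largest mean rises and falls among genes called the same way at all 5 bladder times, the 5 largest each way per tissue difference, the 3 largest each way per step between times, the 5 largest F statistics per F-test, and per list up to 4 members with the smallest p together with called members that went against the list. Only genes with a named symbol were eligible.

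The order of the sample numbers and the BioB, BioC and BioDn hybridization spike-ins split the bladder arrays into 2 series. The largest step between neighbouring arrays was 1.07 log2, and the next largest upward step was 0.58. Series 1 holds 21 vehicle arrays and 0 C1 arrays. Series 2 holds all 24 C1 arrays and 4 vehicle arrays of 168 h, replicates 2 to 5. Within it the level fell from 10.98 to 10.25 between C1 24 h replicates 3 and 4. Treatment and series are therefore nearly inseparable before 168 h. Bladder results are also given against the 4 vehicle arrays of series 2 and with series as a term, which rests on vehicle 168 h replicate 1 of series 1. Both tissues at 5 and 24 h came from the same 20 rats, and the animal was used as a replicate block in an alternative.

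The same steps were run on simulated data with 200 genes changed by known amounts. For the bladder at 48 h, 59.2%, 85.0% and 93.8% of log2 changes of 0.5, 1 and 2 were recovered, with 6 false calls among 162. For the stomach at 5 h these shares were 52.2%, 84.4% and 92.5%, with 9 false calls among 161. A simulated bladder list (48 h, 29 genes raised by 0.5) passed with an estimated correlation (adjusted p = 3.06e-14). In the data 0 of 312 tests did, so this shows no power there. The alternatives covered scaling, floor and offset, dim genes, choice of probe set, spread model, array weights, arrays in the fit, thresholds, replicates left out in turn, series, RNA quality, glandular markers and list test. Python 3.11.15 with matplotlib 3.10.9 drew the plots. Probe sets with no single named gene were left out of the comparisons and counted separately.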

Results

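Female Sprague Dawley rats, an outbred laboratory strain, received vehicle or the compound C1 once a day by gavage, and the urinary bladder was taken at 5, 24, 48, 96 and 168 h after 1, 1, 2, 4 and 7 doses. The non-glandular stomach, the squamous-lined forepart of the rodent stomach, was taken from the same rats at 5 and 24 h. Each group held 5 rats, except C1 at 48 h, of which 4 were profiled. Each array measured the messenger RNA of 1 tissue sample. Mean array intensity was 953.3 ± 187 (SD, n = 5) units for C1 and 1118 ± 28.4 (SD, n = 5) for vehicle bladders at 5 h, and lay between 1007 and 1209 units for the other bladder groups. In the stomach the group means lay between 353.8 and 458.3 units. The comparisons ask which genes differed between C1 and vehicle in each tissue and at each time, whether the difference changed with time, and whether it differed between the tissues. Changes are C1 minus vehicle on the log2 scale. The bladder arrays form 2 series, inferred from sample order and hybridization spike-ins, whose levels overlap. No label names the series. Series 2 holds all 24 C1 arrays and 4 vehicle arrays of 168 h, so treatment and series are confounded before 168 h. Bladder counts, and lists and genes where stated, are also given with series as a term and within series 2, against its 4 vehicle arrays. These 4 arrays serve as control at every time and come from another day than the C1 arrays before 168 h. The series term rests on vehicle 168 h replicate 1 against the 4 others of its group, so before 168 h its values carry that array's own deviation and wider errors (for Etv4 at 5 h the SE is 0.54 instead of 0.26). A call lost with it is therefore no test of the series.

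**Figure D1:**
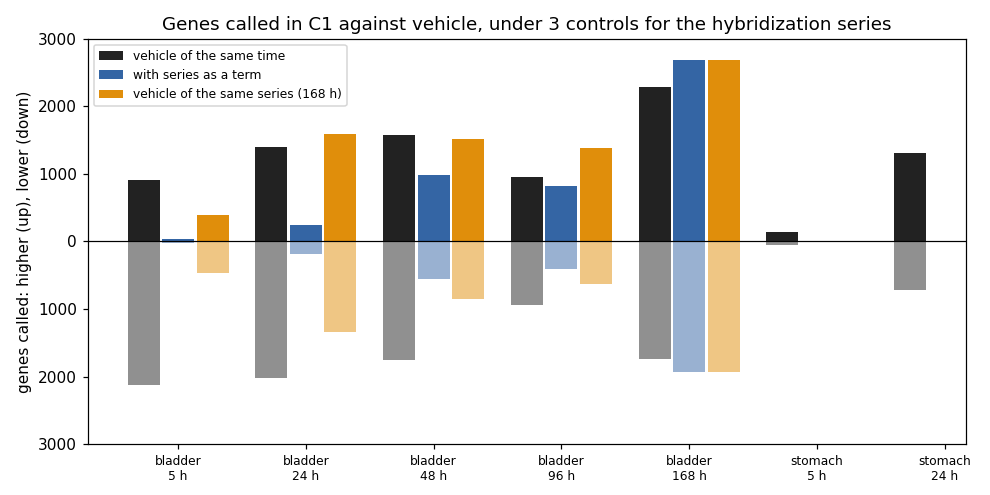
Number of genes called (adjusted p under 0.05) higher or lower under C1 for the 7 comparisons of C1 with vehicle, against the vehicle arrays of the same time, with hybridization series as a term in the model, and against the vehicle arrays of the same series at 168 h. Bladder at 5 h had 3024 genes, and 59 with the series term, which rests on 1 array and widens the errors before 168 h.

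At 5 h in the bladder, after 1 dose, genes that respond to growth factor signalling were higher under C1 (n = 5 against 5). Spry1, Spry2 and Spry4, feedback inhibitors of receptor tyrosine kinases, rose by 0.77 ± 0.12, 0.87 ± 0.14 and 0.98 ± 0.17. Etv4, a transcription factor induced downstream of the ERK kinases, rose by 1.45 ± 0.26. The list of EGFR (epidermal growth factor receptor) ligands and feedback genes held 18 measured members with a median of 0.43, of which 8 rose and 2 fell, and the same numbers passed when adjusted over the list alone (8 and 2). Camera gave it an adjusted p of 7.39e-05, and adjusted p = 0.217 with an estimated correlation. Vehicle replicate 3, which had the highest actin 3'/5' ratio, stood apart low in this list (9.02, the others 9.24 to 9.31). With that ratio as a covariate the median was 0.32 and 0 members were called. The members that fell were Egf, a ligand of the receptor (-0.51 ± 0.12), and Erbb2, a receptor of the same family (-0.55 ± 0.19). The call of Erbb2 was lost without any of 6 single arrays, vehicle replicates 3, 4 and 5 (adjusted p = 0.0614, 0.0814 and 0.0618) and C1 replicates 1, 2 and 4 (0.0874, 0.0504 and 0.0629), and its change was 0.59 with the series term. Within series 2, 5 list members rose and 2 fell (adjusted p = 0.00224), among them Spry1 at 0.91, Spry2 at 1.08, Spry4 at 0.99 and Etv4 at 1.36. With the series term the list median was 0.40 and its adjusted p 0.121.

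Immediate early genes, which respond to stimulation without new protein synthesis, had a median of 0.40 over 25 members at 5 h, and 7 of them rose, also 7 when adjusted over the list alone (adjusted p = 0.000207; adjusted p = 0.789 with an estimated correlation). Junb, a subunit of the transcription factor AP-1, rose by 1.37 ± 0.21, Zfp36, which binds and destabilizes AU-rich messengers, by 0.76 ± 0.15, and Myc, a transcription factor of cell growth, by 0.78 ± 0.18. Within series 2, the list had 2 calls (adjusted p = 0.0838) and the changes of Junb and Zfp36 were 0.37 and 0.18, while Myc was called at 0.72. The list of ribosome biogenesis and MYC targets had a median of 0.16 over 24 members, -0.13 with the values as deposited, and 4 of them rose, also 4 when adjusted over the list alone (adjusted p = 0.0026; adjusted p = 0.901 with an estimated correlation). The smooth muscle and the fibroblast and matrix lists passed at 5 h with 1 called member each, also 1 when adjusted over the list alone, Kcnmb1 at 1.63 ± 0.35 among 20 and Loxl2 at 1.34 ± 0.41 among 23 (adjusted p = 0.0277 and 0.0383; adjusted p = 0.959 with an estimated correlation for each). Their medians were 0.12 and 0.13, but -0.11 for each with the values as deposited, and -0.04 and 0.29 within series 2. With the series term they were -0.04 and -0.91, where the array behind that term stood apart in the fibroblast list (11.07, the others of its group 12.1 to 12.45). Without vehicle replicate 3 the call of Loxl2, an enzyme that crosslinks collagen, was lost (1.13, adjusted p = 0.0513). Its change was -1.13 with the series term and -0.29 with the actin covariate, which put the fibroblast list at -0.52 (adjusted p = 8.85e-07).

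The largest rises at 5 h among genes whose groups did not overlap were those of Herc1, a large ubiquitin ligase, at 2.50 ± 0.28, Pdlim5 at 1.90 ± 0.33 and Hook3, above the floor on 1 of 5 vehicle arrays, at 1.90 ± 0.22. The largest falls were those of Rttn, above the floor on 1 of 5 C1 arrays, at -1.77 ± 0.52, Pou2f1, a transcription factor above the floor on 3 of 5 C1 arrays, at -1.49 ± 0.31, and Pcnt, a centrosome scaffold above the floor on 2 of 5, at -1.38 ± 0.27. Within series 2, none of these 6 was called, and Herc1 was at -0.24. Of the 20 genes of this kind, Samd11 at -1.23 ± 0.16 and Ctns, the lysosomal cystine transporter above the floor on 4 of 5 C1 arrays, at -1.30 ± 0.22 were called there too, at -0.77 and -0.70.

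limma called 3024 of 11277 genes at 5 h, 903 higher and 2121 lower. With the series term 59 were called (33 higher, 26 lower), and within series 2 there were 858 (398 and 460), of which 416 were shared with the 3024. The actin 3'/5' ratio, a sign of RNA degradation, was 0.372 ± 0.0363 (SD, n = 5) log2 units under C1 and 1.46 ± 0.453 (SD, n = 5) under vehicle at 5 h (two-sided exact p = 0.00794, the smallest the design allows; 0.0794 after adjustment over 30 measures), and with it as a covariate 254 genes were called (118 higher, 136 lower). Falls outnumbered rises in each setting but the series term. Their share depended on the scaling, with 213 higher and 4026 lower for the values as deposited and 527 and 2939 after centring each array. It also depended on the probe sets, with 1522 and 1895 for the mean of a gene's probe sets, and 2502 and 2584 for every probe set on its own. The median of all genes was -0.08 after quantile normalization and -0.31 as deposited.

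At 24 h in the bladder, still after 1 dose, genes of DNA replication, protein folding, ribosome assembly and cholesterol synthesis were higher under C1 (n = 5 against 5). Mcm6, a subunit of the replicative helicase, rose by 1.80 ± 0.33, Fen1, a flap endonuclease, by 1.26 ± 0.23, and Uhrf1, which maintains DNA methylation and was above the floor on 4 of 5 C1 arrays, was at least 2.57-fold higher. Of the 29 measured members of the DNA replication list 25 rose, 26 when adjusted over the list alone, with a median of 0.95 (adjusted p = 2.6e-16; adjusted p = 0.497 with an estimated correlation). Of 17 members of the unfolded protein response list 13 rose, 14 when adjusted over the list alone, with a median of 0.66 (adjusted p = 5.76e-11; adjusted p = 0.497 with an estimated correlation). Of 24 ribosome biogenesis and MYC targets 14 rose, 15 when adjusted over the list alone, with a median of 0.38 (adjusted p = 3.45e-09; adjusted p = 0.497 with an estimated correlation). Of 20 cholesterol synthesis genes 13 rose, and 16 rose and 1 fell when adjusted over the list alone, with a median of 0.58 (adjusted p = 1.79e-08; adjusted p = 0.533 with an estimated correlation). Within series 2, the members called higher were 25 for DNA replication, 13 for the unfolded protein response, 18 for ribosome biogenesis and 16 for cholesterol synthesis, and the lists passed with medians of 0.91, 0.53, 0.41 and 0.56. The members called higher with the series term were 0, 0, 4 and 2, and the medians 0.93, 0.41, 0.56 and 0.83.

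EGFR family genes went both ways at 24 h. Areg, amphiregulin, rose by 2.16 ± 0.41 (above the floor on 4 of 5 vehicle arrays), and Nrg1, a ligand of the related ERBB receptors, by 1.84 ± 0.30 (also 4 of 5). Of the 18 EGFR ligand and feedback genes 11 rose and 3 fell, 11 and 4 when adjusted over the list alone, with a median of 0.55 (adjusted p = 0.00209; adjusted p = 0.497 with an estimated correlation). Those that fell were Egf (-0.41 ± 0.12), the receptor Egfr (-0.36 ± 0.11, not called within series 2) and Lrig3 (-0.33 ± 0.12). The wound and matrix remodelling list had 9 of 15 members higher, 10 when adjusted over the list alone, and a median of 0.95 (adjusted p = 3.8e-05; adjusted p = 0.533 with an estimated correlation). In it Plaur, the urokinase receptor, rose by 1.62 ± 0.33, Mmp3, the matrix metalloproteinase stromelysin 1, by 3.25 ± 0.79 (above the floor on 4 of 5 C1 arrays) and Krt6c, a keratin of activated keratinocytes matched to the list through an older symbol, by 2.43 ± 0.59. Of 15 basal epithelial markers 9 rose and 1, Dst, fell (-0.47 ± 0.16), the same when adjusted over the list alone, with a median of 0.39 (adjusted p = 0.000563; adjusted p = 0.533 with an estimated correlation). Of 36 mitosis genes 9 rose, 6 when adjusted over the list alone, with a median of 0.43 (adjusted p = 0.000326; adjusted p = 0.959 with an estimated correlation). Mad2l1, a spindle checkpoint protein, rose by 1.06 ± 0.22 and Cdk1 by 1.35 ± 0.40. These 4 lists passed within series 2 too, with 10 rises and 2 falls, 10 rises, 10 rises and 1 fall, and 6 rises. With the series term the adjusted p was 0.389 for the EGFR list, 0.0999 for the wound list, 0.000193 for basal markers and 0.46 for mitosis. Areg was then at 2.04 and Nrg1 at 1.30 (adjusted p = 0.143 and 0.2).

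Smaller shifts at 24 h were found in proteasome genes, with 8 of 25 higher, 8 when adjusted over the list alone, and a median of 0.11 (adjusted p = 0.000326; adjusted p = 0.789 with an estimated correlation), and in epithelial junctions, with 4 of 18 higher and 1, Cldn8, lower (-0.46 ± 0.14), 7 and 1 when adjusted over the list alone, and a median of 0.23 (adjusted p = 0.0122; adjusted p = 0.901 with an estimated correlation). Of 11 heat shock genes 6 rose, 6 when adjusted over the list alone, with a median of 0.30 (adjusted p = 0.0081; adjusted p = 0.68 with an estimated correlation), and 2 rose and 1 fell within series 2 (adjusted p = 0.624). PPAR targets and genes of fatty acid oxidation went down, with 11 of 24 lower and 1 higher, the same when adjusted over the list alone, and a median of -0.22 (adjusted p = 0.0351; adjusted p = 0.901 with an estimated correlation). Acot1, an acyl-CoA thioesterase, fell by 1.65 ± 0.26 and Pdk4, the kinase that inhibits pyruvate dehydrogenase, was at -1.12 ± 0.22, while Plin2, a lipid droplet protein, rose by 0.95 ± 0.21. All 3 were called in the same direction within series 2. The adjusted p with the series term was 0.0131 for proteasome, 1.78e-06 for junction, 0.368 for heat shock and 0.435 for PPAR genes.

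Gcnt3, a glycosyltransferase of mucin synthesis, rose by 2.17 ± 0.41 at 24 h and Gkn1, a gastrokine of gastric surface mucous cells, by 1.86 ± 0.37. Olig1, a transcription factor above the floor on 2 of 5 C1 arrays, was lower by log2 -2.46 ± 0.43, and Scnn1g, the gamma subunit of the epithelial sodium channel, by log2 -1.68 ± 0.30. These 4 were called within series 2, at 2.61, 2.21, -1.78 and -1.72. Pa2g4 rose by 2.28 ± 0.22 and was called there at 0.69, whereas Ankrd11 (1.83 ± 0.27) and Herc1 (1.87 ± 0.28) were at -0.22 and -0.51. limma called 3422 genes at 24 h, 1398 higher and 2024 lower, 434 with the series term (246 and 188) and 2919 within series 2 (1584 and 1335), of which 1866 were shared. Scaling changed the share of rises, with 644 higher and 485 lower as deposited and 929 and 1965 after centring each array. The Gapdh and actin 3'/5' ratios were lower under C1 by log2 -0.14 and -0.34 at 24 h and -0.14 and -0.38 at 48 h, none past the threshold after adjustment. The two-sided exact p was 0.00794 and 0.0238 (0.0794 and 0.102 adjusted) at 24 h and 0.0476 and 0.0952 (0.179 and 0.258) at 48 h.

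At 48 h, after 2 doses, genes of cell division rose in the bladder (n = 4 against 5). Mki67, the proliferation antigen Ki-67, rose by 3.81 ± 0.43 (above the floor on 1 of 5 vehicle arrays), the cyclins Ccnb2 and Ccna2 by 3.81 ± 0.51 (4 of 5) and 3.66 ± 0.39 (1 of 5), Pclaf, a partner of the replication clamp, by 3.89 ± 0.52 (4 of 5), and the mitotic kinesin Kif20a by 3.59 ± 0.44 (1 of 5). For Mki67, Ccna2 and Kif20a, at the floor on most vehicle arrays, the change is in effect a lower bound. Of 36 mitosis genes 35 rose, 36 when adjusted over the list alone, with a median of 2.70 (adjusted p = 1.05e-44; adjusted p = 0.155 with an estimated correlation). Foxm1, a transcription factor of mitotic genes, was at least 2.39-fold higher and Bub1b, a spindle checkpoint kinase, at least 4.36-fold higher. Of 29 DNA replication genes 27 rose, 28 when adjusted over the list alone, with a median of 1.21 (adjusted p = 2.14e-18; adjusted p = 0.497 with an estimated correlation). Within series 2, 36 mitosis and 28 replication genes rose (medians 2.71 and 1.26), and with the series term 28 and 13 (medians 2.50 and 1.19).

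**Figure D2:**
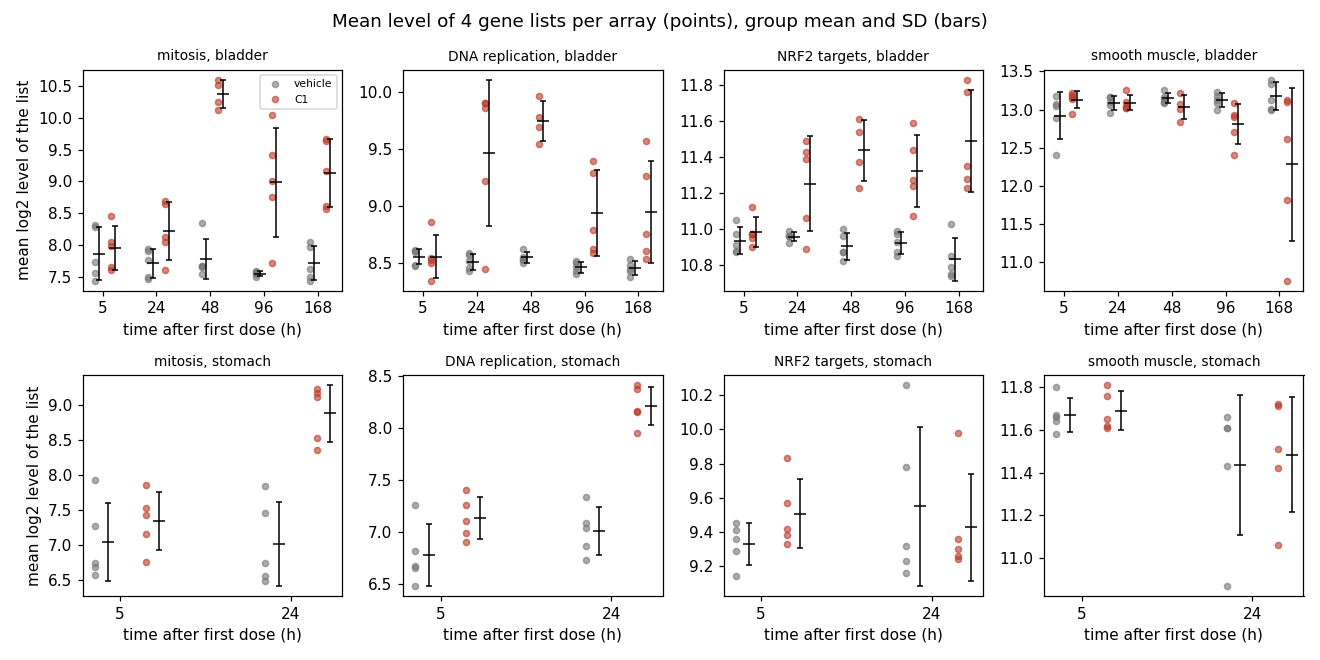
Mean log2 level of the genes of 4 lists (mitosis, DNA replication, NRF2 targets, smooth muscle) per array against time in hours for vehicle and C1, bladder in the top panels and stomach in the bottom panels, where points are arrays and bars the group mean with its SD. In the bladder at 48 h the C1 arrays lay between 10.12 and 10.60 for mitosis and the vehicle arrays between 7.55 and 8.34.

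Epithelial genes changed at 48 h as well. Of 18 epithelial junction genes 11 rose, 13 when adjusted over the list alone, with a median of 0.48 (adjusted p = 1.4e-05; adjusted p = 0.587 with an estimated correlation). Of 15 basal epithelial markers 7 rose and 1, Dst, fell (-0.46 ± 0.17), 8 and 1 when adjusted over the list alone, with a median of 0.36 (adjusted p = 0.00706; adjusted p = 0.685 with an estimated correlation). The basal keratins Krt14 and Krt5 rose by 2.42 ± 0.55 and 0.94 ± 0.20. Of 18 umbrella cell markers, genes of the superficial urothelium, 5 rose, 5 when adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0263; adjusted p = 0.901 with an estimated correlation). Within series 2 the members that rose were 12, 7 and 4, with an adjusted p of 0.053 for the umbrella list, and with the series term 12, 7 and 7. Of 15 wound and matrix genes 5 rose, 5 when adjusted over the list alone, with a median of 0.53 (adjusted p = 0.0383; adjusted p = 0.901 with an estimated correlation). The median was 0.42 within series 2 and -0.01 with the series term. Krt6c rose by 3.35 ± 0.63, Mmp3 by 4.38 ± 0.84 (3.39 with the series term, adjusted p = 0.16) and the collagenase Mmp13 by 2.79 ± 0.74 (above the floor on 4 of 5 vehicle arrays).

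Targets of NRF2, the transcription factor of the response to oxidants and electrophiles, had 12 of 24 members higher at 48 h, 13 when adjusted over the list alone, and a median of 0.40 (adjusted p = 0.000295; adjusted p = 0.533 with an estimated correlation). The glutathione transferases Gstm1 and Gsta3 rose by 0.97 ± 0.15 and 2.20 ± 0.36, and Tkt and Pgd, enzymes of the pentose phosphate pathway, by 0.64 ± 0.12 and 0.47 ± 0.10. Of 20 cholesterol synthesis genes 11 rose, 13 when adjusted over the list alone, with a median of 0.42 (adjusted p = 0.000105; adjusted p = 0.88 with an estimated correlation). Within series 2, 13 NRF2 targets and 11 cholesterol genes rose, and with the series term 9 and 5. Of 25 proteasome genes 5 rose and 1, Psmc2, fell (-0.19 ± 0.06), the same when adjusted over the list alone, with a median of 0.10, -0.01 after centring each array (adjusted p = 0.0127; adjusted p = 0.901 with an estimated correlation).

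The largest rise at 48 h was that of Gkn2, a second gastrokine, which was 27.8-fold higher (4.80 ± 0.68, above the floor on 3 of 5 vehicle arrays, 4.86 within series 2). Among the falls were Olig1 (-3.04 ± 0.46, above the floor on 2 of 4 C1 arrays), Aldh3a1, an aldehyde dehydrogenase (-2.11 ± 0.56, 3 of 4), Car11 (-1.74 ± 0.35) and Txnrd3, a thioredoxin reductase (-1.50 ± 0.16), all called within series 2. limma called 3328 genes at 48 h, 1578 higher and 1750 lower, 1542 with the series term (984 and 558) and 2370 within series 2 (1520 and 850), of which 1602 were shared. Scaling changed the share of rises, with 785 higher and 256 lower as deposited and 911 and 2345 after centring each array.

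At 96 h, after 4 doses, division genes were still higher in the bladder, and mast cell genes rose (n = 5 against 5). Ccnb2 rose by 2.56 ± 0.48 (above the floor on 4 of 5 vehicle arrays) and Nusap1, a spindle protein, by 2.35 ± 0.41, and Cdkn3 was at least 5.58-fold higher. Of 36 mitosis genes 31 rose, 34 when adjusted over the list alone, with a median of 1.32 (adjusted p = 3.87e-25; adjusted p = 0.497 with an estimated correlation). Of 29 DNA replication genes 7 rose, 10 when adjusted over the list alone, with a median of 0.42 (adjusted p = 3.81e-05; adjusted p = 0.901 with an estimated correlation). Of 8 mast cell and eosinophil genes 5 rose, 6 when adjusted over the list alone, with a median of 1.14 (adjusted p = 0.00146; adjusted p = 0.533 with an estimated correlation). Fcer1a, a chain of the high-affinity IgE receptor, rose by 0.91 ± 0.24 (above the floor on 2 of 5 vehicle arrays) and Tpsab1, a mast cell tryptase, by 1.49 ± 0.41 (3 of 5). Tpsab1 was not called within series 2 (1.13, adjusted p = 0.0626). There, 31 mitosis, 6 replication and 5 mast cell genes rose (medians 1.18, 0.45 and 1.08), and with the series term 2 mitosis genes (median 1.24). The mast cell list had an adjusted p of 0.379 with the series term. The macrophage list passed with a median of 0.52 over 18 members (adjusted p = 0.0132; adjusted p = 0.959 with an estimated correlation), although limma called 0 of them and 4 lay under an unadjusted p of 0.05. Within series 2 its median was 1.02 with 10 members higher, and with the series term -0.71.

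Epithelial genes and NRF2 targets were higher at 96 h too. Of 18 epithelial junction genes 8 rose, 9 when adjusted over the list alone, with a median of 0.42 (adjusted p = 8.29e-06; adjusted p = 0.574 with an estimated correlation). Of 15 basal markers 7 rose, and 8 rose and 1 fell when adjusted over the list alone, with a median of 0.45 (adjusted p = 0.000239; adjusted p = 0.497 with an estimated correlation). Of 24 NRF2 targets 9 rose and 1, Me1, fell (-0.44 ± 0.14), 9 and 2 when adjusted over the list alone, with a median of 0.22 (adjusted p = 0.00047; adjusted p = 0.533 with an estimated correlation). The conjugate exporter Abcc3 rose by 1.52 ± 0.23 and the quinone reductase Nqo1 by 0.79 ± 0.20. Of 15 wound and matrix genes 3 rose, 5 when adjusted over the list alone, with a median of 0.52 (adjusted p = 0.00914; adjusted p = 0.901 with an estimated correlation). The calls of all 3, Mmp3 (2.84 ± 0.79), Krt6c (2.12 ± 0.59) and Mmp13 (2.27 ± 0.70), were lost without C1 replicate 2 (2.44, 1.78 and 1.94, adjusted p = 0.0511, 0.0548 and 0.0795). That of Mmp13 was also lost without C1 replicate 5 (adjusted p = 0.0587) and without vehicle replicate 1 or 3 (adjusted p = 0.055 and 0.0529). Within series 2, 11 junction genes, 8 basal markers, 12 NRF2 targets and 4 wound genes rose, and with the series term 10, 6, 5 and 1.

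Gkn2 rose by 3.10 ± 0.64 at 96 h (above the floor on 2 of 5 vehicle arrays), Lgals4, a galectin, by 2.97 ± 0.57, Upk3bl1, a uroplakin-like gene, by 2.54 ± 0.56 and Apod, apolipoprotein D, by 2.34 ± 0.37. Olig1 was at -3.40 ± 0.43 (above the floor on 2 of 5 C1 arrays), Aldh3a1 at -1.91 ± 0.53 and Cyp3a18, a cytochrome P450, at -1.55 ± 0.26 (3 of 5). Within series 2 all but Aldh3a1 (-0.96, adjusted p = 0.19) were called. limma called 1897 genes at 96 h, 960 higher and 937 lower, 1220 with the series term (814 and 406) and 2019 within series 2 (1389 and 630), of which 861 were shared. Without C1 replicate 2 the count was 1161 (613 and 548). Scaling changed the share of rises, with 633 higher and 62 lower as deposited and 561 and 929 after centring each array.

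At 168 h, after 7 doses, smooth muscle genes were lower in the bladder while division, junction, NRF2 and basal genes were higher (n = 5 against 5). All 20 measured smooth muscle genes fell, 20 when adjusted over the list alone, with a median of -0.88 (adjusted p = 3.52e-09; adjusted p = 0.748 with an estimated correlation). Lmod1, an actin nucleator of muscle, was at -1.55 ± 0.31, Smtn, smoothelin, at -1.16 ± 0.25 and Myl9, a myosin light chain, at -0.88 ± 0.21. These errors and calls pool all bladder arrays and do not measure the spread of C1 here (list means 10.76 to 13.12). Of 36 mitosis genes 32 rose, 33 when adjusted over the list alone, with a median of 1.32 (adjusted p = 2.28e-14; adjusted p = 0.587 with an estimated correlation), Kif20a by 2.47 ± 0.41 (above the floor on 1 of 5 vehicle arrays). Of 18 epithelial junction genes 15 rose, 15 when adjusted over the list alone, with a median of 0.59 (adjusted p = 4.12e-06; adjusted p = 0.56 with an estimated correlation). Of 24 NRF2 targets 16 rose, 16 when adjusted over the list alone, with a median of 0.54 (adjusted p = 3.81e-05; adjusted p = 0.497 with an estimated correlation). Of 15 basal markers 12 rose and 1, Dst, fell (-0.74 ± 0.16), 13 and 1 when adjusted over the list alone, with a median of 0.58 (adjusted p = 0.000563; adjusted p = 0.533 with an estimated correlation). Lamb3 rose most, by 1.56 ± 0.17. Of 29 DNA replication genes 11 rose, 11 when adjusted over the list alone, with a median of 0.45 (adjusted p = 0.00254; adjusted p = 0.959 with an estimated correlation). Of 15 wound genes 7 rose, 7 when adjusted over the list alone, with a median of 0.56 (adjusted p = 0.031; adjusted p = 0.901 with an estimated correlation). Of 23 fibroblast and matrix genes 3 fell and 1 rose, the same when adjusted over the list alone, with a median of -0.36 (adjusted p = 0.0196; adjusted p = 0.959 with an estimated correlation). Postn, periostin, was at -0.87 ± 0.15 and Thy1 at 0.80 ± 0.17.

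Within series 2 at 168 h, where the 4 vehicle arrays are of the same day, 20 smooth muscle genes fell. There, 32 mitosis, 16 junction, 16 NRF2, 13 basal and 11 replication genes rose and 14 fibroblast and matrix genes fell. The wound list then had 6 rises and an adjusted p of 0.101. C1 replicates 5 and 1 had the lowest mean correlation with the other bladder arrays (0.875 and 0.923). Without both, 1 smooth muscle gene fell (median -0.19, adjusted p = 0.00238), and 18 mitosis genes (median 1.01), 7 junction genes (0.44), 9 NRF2 targets (0.44) and 4 basal markers (0.49) rose with their lists past the test. The replication (0.07, adjusted p = 0.184), fibroblast (-0.10, 0.661) and wound lists (0.43, 0.0546) did not pass without them.

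Among the largest rises at 168 h were Mmp13 (3.74 ± 0.70) and Mmp3 (3.40 ± 0.79), each above the floor on 3 of 5 vehicle arrays, Upk3bl1 (3.32 ± 0.56), Gkn2 (2.84 ± 0.64, 1 of 5), Lgals4 (2.83 ± 0.57) and Ivl, involucrin of the cornified envelope (2.65 ± 0.45, 1 of 5). The largest falls included Olig1 (-2.09 ± 0.43, above the floor on 1 of 5 C1 arrays), Car11 (-1.97 ± 0.33, 1 of 5), Slc2a4, the insulin-regulated glucose transporter (-1.91 ± 0.35, 4 of 5), Kcnip2 (-1.91 ± 0.38) and Foxp2 (-1.87 ± 0.36). All of these were called within series 2. Without the pair of C1 arrays of low correlation Slc2a4, Kcnip2 and Foxp2 were at -1.02, -1.13 and -0.83, still called, and Mmp3 at 2.61 was not (adjusted p = 0.057). limma called 4029 genes, 2290 higher and 1739 lower, 4610 with the series term or within series 2 (2683 and 1927), of which 3844 were shared, and 1118 without that pair (589 and 529, 1085 shared). Scaling changed the share of rises, with 1763 higher and 671 lower as deposited and 2733 and 1298 after centring each array.

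Across the 5 bladder times, 65 genes were called higher every time and 55 lower, and 14 and 11 of these were also called every time within series 2, where the same 4 vehicle arrays serve each time and build in part of that agreement. Prss22, a secreted serine protease, rose by 1.40 ± 0.25, 1.74 ± 0.25, 1.86 ± 0.26, 1.10 ± 0.25 and 1.70 ± 0.25 at 5, 24, 48, 96 and 168 h, and Etv4 by 1.45 ± 0.26, 1.80 ± 0.26, 1.83 ± 0.28, 1.12 ± 0.26 and 1.39 ± 0.26, each called at every time within series 2. Neither was called at 5, 24 or 96 h with the series term (adjusted p = 0.381, 0.0952 and 0.347 for Prss22 and 0.246, 0.0566 and 0.198 for Etv4). Alox12, a lipoxygenase, was at -0.87 ± 0.25, -0.96 ± 0.25, -1.04 ± 0.27, -0.85 ± 0.25 and -1.72 ± 0.25 at the 5 times, and between -1.50 and -1.71 within series 2, called each time, but at -0.32, -0.40, -0.49 and -0.30 at 5 to 96 h with the series term, not called. At 96 h its call was lost without vehicle replicate 3 (-0.76, adjusted p = 0.0527) or C1 replicate 2 (-0.74, 0.0647).

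**Figure D3:**
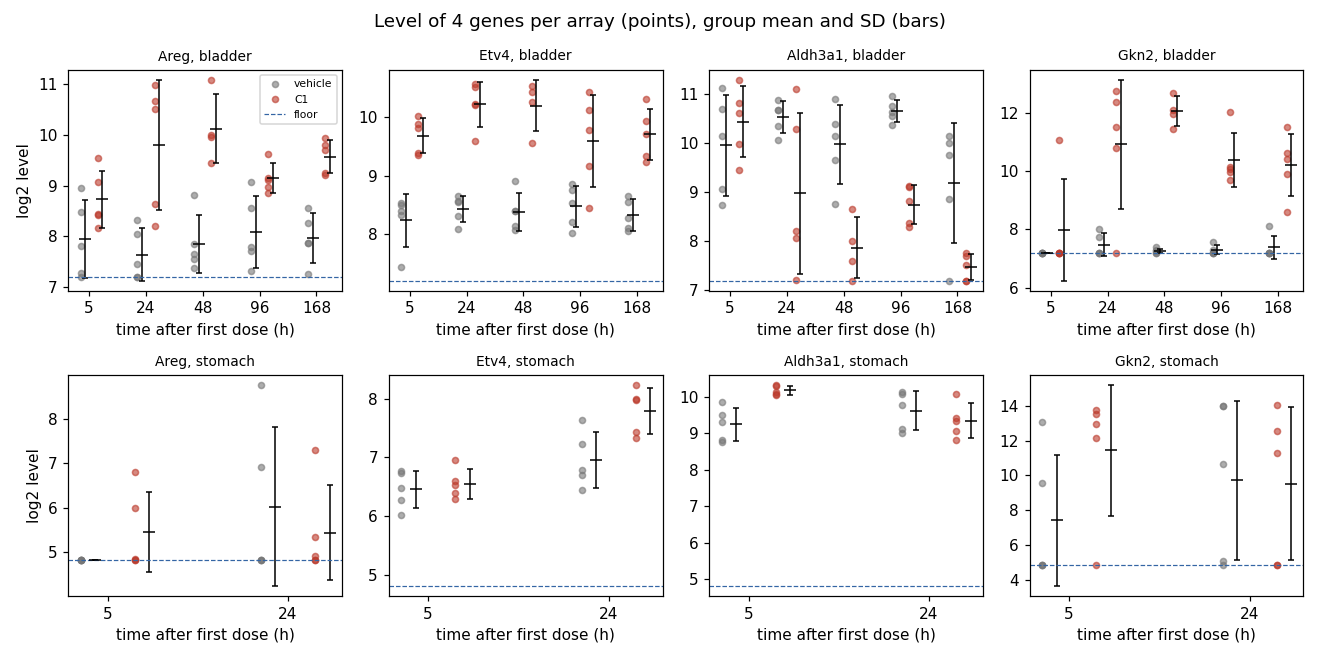
Log2 level of Areg, Etv4, Aldh3a1 and Gkn2 per bladder and stomach array against time in hours for vehicle and C1, where points are arrays, bars the group mean with its SD and the dashed line the floor. For Etv4 the C1 bladder arrays at 5 h lay between 9.35 and 10.02 and the vehicle arrays between 7.43 and 8.53.

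In the non-glandular stomach at 5 h, ribosome assembly genes rose (n = 5 against 5). Of 24 ribosome biogenesis and MYC targets 14 rose, 23 when adjusted over the list alone, with a median of 0.51 (adjusted p = 1.19e-30; adjusted p = 0.136 with an estimated correlation). Rrp12 rose by 1.03 ± 0.14, Nop56 by 0.94 ± 0.13 and Nop58 by 0.68 ± 0.10, and outside the list Heatr1, a factor of ribosomal RNA transcription, rose by 1.12 ± 0.18. Of 30 DNA replication genes 3 rose, 10 when adjusted over the list alone, with a median of 0.32 (adjusted p = 1.58e-07; adjusted p = 0.755 with an estimated correlation). Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (AhR), rose by 2.25 ± 0.48. Its call was lost without vehicle replicate 2 or 3 (2.04 and 1.92, adjusted p = 0.0683 and 0.0575) or C1 replicate 2 or 4 (1.99 and 2.06, 0.0604 and 0.0597). It was the 1 called member of 6 AhR targets, 3 when adjusted over the list alone, with a median of 0.74 (adjusted p = 0.000222; adjusted p = 0.136 with an estimated correlation), where Aldh3a1 was at 0.93 ± 0.26 and Nqo1 at 0.89 ± 0.29. Among the falls were Mycl, a MYC family member (-1.24 ± 0.23), and Hs3st6 (-0.72 ± 0.11).

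Other lists passed in the stomach at 5 h with 1 or 0 called members. Of 14 basal markers 1, Itga6, rose (0.78 ± 0.14), 5 when adjusted over the list alone, with a median of 0.26 (adjusted p = 0.00607; adjusted p = 0.482 with an estimated correlation). Of 17 unfolded protein response genes 1 rose, 4 when adjusted over the list alone, with a median of 0.20 (adjusted p = 1.91e-05; adjusted p = 0.901 with an estimated correlation). That gene was Creld2, at 0.85 ± 0.20, with an adjusted p between 0.0661 and 0.0991 without any of 7 single arrays, vehicle replicates 1, 2 and 3 and C1 replicates 1, 2, 4 and 5. limma called 0 members, also 0 when adjusted over the list alone, of 24 PPAR and fatty acid oxidation genes (median -0.21, 8 under an unadjusted p of 0.05; adjusted p = 0.000132; adjusted p = 0.533 with an estimated correlation), 36 mitosis genes (median 0.29, 1 under it; adjusted p = 0.00193; adjusted p = 0.959 with an estimated correlation), and 20 junction genes (median 0.19, 2 under it; adjusted p = 0.0328; adjusted p = 0.959 with an estimated correlation). In the junction list C1 replicate 1 stood apart high (10.16, the others 9.76 to 9.82). Its median was 0.06 with the glandular mean as a covariate (adjusted p = 0.91).

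The Gapdh 3'/5' ratio in the stomach at 5 h was higher under C1 by 0.10 (two-sided exact p = 0.0159, and 0.0954 after adjustment). Markers of the glandular stomach, a neighbouring tissue, were high on 6 of the 20 stomach arrays (1 vehicle and 2 C1 at 5 h, 2 vehicle and 1 C1 at 24 h). Of the rest, C1 replicates 4 and 5 at 5 h (7.62, 8.38) and 3 and 4 at 24 h (8.06, 7.20) exceeded all vehicle arrays (6.27 at most), an imbalance kept without the 6. The marker mean was higher by 2.45 log2 under C1 at 5 h and lower by log2 -0.85 at 24 h (two-sided exact p = 0.175 and 0.77). The glandular list passed at 5 h with a median of 2.72 over 13 members (adjusted p = 0.0128; adjusted p = 0.959 with an estimated correlation). In it limma called 0 genes, and 0 lay under an unadjusted p of 0.05. limma called 184 of 11633 genes at 5 h, 133 higher and 51 lower, and 117 (74 and 43) without the arrays high in glandular markers. Without single arrays the count was 95 and 106 (vehicle replicates 1 and 2) and 105, 117 and 77 (C1 replicates 1, 2 and 5). It was 81 higher and 6 lower as deposited, 71 and 65 after centring each array, and 479 and 293 with array quality weights, and the median of all genes was -0.01 after quantile normalization and 0.10 as deposited.

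At 24 h, cell division and DNA replication genes were higher in the stomach (n = 5 against 5). All 36 mitosis genes rose, 36 when adjusted over the list alone, with a median of 1.86 (adjusted p = 3.33e-28; adjusted p = 0.497 with an estimated correlation). Among them were Birc5, survivin (2.57 ± 0.47, above the floor on 4 of 5 vehicle arrays), the kinase Ttk (2.42 ± 0.36, 3 of 5) and Mad2l1 (1.96 ± 0.26). Of 30 DNA replication genes 29 rose, 30 when adjusted over the list alone, with a median of 1.18 (adjusted p = 3.3e-26; adjusted p = 0.287 with an estimated correlation). Of 24 ribosome biogenesis and MYC targets 19 rose, 21 when adjusted over the list alone, with a median of 0.57 (adjusted p = 1.17e-15; adjusted p = 0.482 with an estimated correlation). Of 25 proteasome genes 14 rose, 17 when adjusted over the list alone, with a median of 0.24 (adjusted p = 2.93e-07; adjusted p = 0.555 with an estimated correlation). Of 24 PPAR and fatty acid oxidation genes 10 fell and 1, Plin2, rose (0.62 ± 0.18), 11 and 1 when adjusted over the list alone, with a median of -0.41 (adjusted p = 8.29e-06; adjusted p = 0.497 with an estimated correlation).

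Some members of 5 further lists rose in the stomach at 24 h. Of 11 heat shock genes 5 rose, 5 when adjusted over the list alone, with a median of 0.37 (adjusted p = 0.00227; adjusted p = 0.685 with an estimated correlation). Of 20 cholesterol synthesis genes 5 rose, 7 when adjusted over the list alone, with a median of 0.36 (adjusted p = 0.00362; adjusted p = 0.92 with an estimated correlation). Of 17 unfolded protein response genes 6 rose, 7 when adjusted over the list alone, with a median of 0.36 (adjusted p = 0.0275; adjusted p = 0.959 with an estimated correlation). Of 13 wound and matrix genes 4 rose, 5 when adjusted over the list alone, with a median of 0.67 (adjusted p = 0.0136; adjusted p = 0.497 with an estimated correlation). Inhba, the activin A subunit, was at 2.19 ± 0.57 and Timp1, a protease inhibitor, at 1.36 ± 0.36. Of 26 squamous differentiation genes 4 rose, 5 when adjusted over the list alone, with a median of 0.23 (adjusted p = 0.0277; adjusted p = 0.959 with an estimated correlation), but -0.01 and an adjusted p of 0.801 without the arrays high in glandular markers. In it Sprr1b, a cornified envelope precursor, rose by 3.86 ± 0.52.

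Mlf1 was at least 6.36-fold higher in the stomach at 24 h, and Fosl1, an AP-1 subunit above the floor on 2 of 5 vehicle arrays, rose by 2.46 ± 0.45. Among the falls were Smpdl3a (-1.54 ± 0.24), Smoc1 (-1.50 ± 0.28), the retinol saturase Retsat (-1.39 ± 0.25) and Ephx2, the soluble epoxide hydrolase (-2.19 ± 0.62, above the floor on 4 of 5 C1 arrays), whose call was lost without C1 replicate 4 (-1.77, adjusted p = 0.0645). limma called 2023 genes, 1308 higher and 715 lower. It called 764 higher and 162 lower as deposited, 732 and 210 in a fit of these groups alone, and 1788 and 1549 with array quality weights. Of the genes called in the bladder and in the stomach at 24 h, 540 were higher in both, where 157.3 would be shared if the calls were independent, and 404 lower in both against 127.8. The tissues came from the same rats, so independence is not the value that no shared change would give. Within the stomach, 115 genes were higher at both times against 15 under independence.

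The change under C1 differed between bladder and stomach for 723 genes at 5 h (238 higher and 485 lower in the bladder) and 368 at 24 h (107 and 261). With every probe set on its own the split was 1121 and 684 at 5 h and 345 and 350 at 24 h. At 5 h it was 35 and 1183 as deposited and 27 and 30 with the actin covariate. At 24 h mitosis genes had a smaller change in the bladder, with a median difference of -1.25 over 36 members, 13 of them lower, 27 when adjusted over the list alone. The bladder arrays at 24 h lay close to the floor for these genes (list means 7.46 to 8.69, floor 7.20), where a change is hard to measure. The difference was -2.40 ± 0.49 for Birc5, -2.40 ± 0.46 for Bub1b and -2.32 ± 0.48 for Plk1, a mitotic kinase. Of these, only Plk1 stayed called with a floor of 1 or the 5th percentile. Sprr1b differed by -4.08 ± 0.54, with 3.86 in the stomach and -0.23 in the bladder, and by -3.98 with the series term. Tanc2 (2.22 ± 0.23) and Herc1 (1.93 ± 0.29) were higher in the bladder at 24 h, at 0.70 and -0.02 with the series term. At 5 h Gpatch4 differed by -1.68 ± 0.26. Cyp1a1 differed by -3.50 ± 1.00, at 2.25 in the stomach and -1.26 in the bladder, a call lost in 5 of 10 fits without 1 rat (highest adjusted p = 0.0858). Of 24 ribosome biogenesis and MYC targets 6 had a lower change in the bladder at 5 h, 9 when adjusted over the list alone, with a median difference of -0.34. With the series term 21 genes differed at 5 h (11 and 10) and 89 at 24 h (41 and 48), and with the animal as a block 561 at 24 h (177 and 384). Without 1 rat, the count at 5 h was 387 and 462 (vehicle replicates 3 and 4), 443 and 480 (C1 replicates 2 and 5), and at 24 h 240 (vehicle replicate 1), 221 and 212 (C1 replicates 4 and 5).

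The change under C1 in the bladder varied with time for 3951 genes (limma's F-test), 2049 with the series term. The linker histone H1f10, above the floor on all arrays, had an F of 22.5. The F of Foxm1 (29.2), Sgo1 (23.8), Aspm (23.3) and Kif18b (22.8) was larger, but groups at the floor had a spread of 0, and with a floor of 1 it was 7.08, 5.42, 2.68 and 1.56, against 22.3 for H1f10. From 24 to 48 h, 192 genes changed (153 higher, 39 lower, 230 with the series term, 337 without C1 24 h replicate 3), among them Kif20a (3.46 ± 0.60), Pttg1, securin (3.17 ± 0.48), and Maff, a small MAF factor (-2.04 ± 0.40). Of 36 mitosis genes 29 rose in this step, 35 when adjusted over the list alone, with a median of 2.03. From 48 to 96 h, 96 genes changed (29 and 67, 117 with the series term), with Tnfaip8l2, a regulator of immune signalling, at 1.76 ± 0.39, P2ry12, a receptor for ADP, at 1.46 ± 0.32 and Birc5 at -1.79 ± 0.41. The call of Birc5 was lost in 4 of 19 fits without 1 array (highest adjusted p = 0.0732). Mitosis genes had a median of -1.25 in this step with 9 lower, 22 when adjusted over the list alone. The count of 96 became 63 without vehicle 48 h replicate 2, 49 and 38 without C1 48 h replicates 2 and 3, and 44 and 50 without C1 96 h replicates 3 and 5.

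From 5 to 24 h, 146 genes changed in the bladder (90 higher, 56 lower, 161 with the series term, 223 and 6 as deposited, and 0 with the actin covariate), among them Ccne1, a cyclin of S phase entry (1.86 ± 0.44), and Olig1 (-2.45 ± 0.61). Their calls were lost in 7 and 12 of 20 fits without 1 array (highest adjusted p = 0.0905 and 0.0983). DNA replication genes had a median of 0.89 with 7 higher, 24 when adjusted over the list alone. This count was 10, 83 and 64 without vehicle 5 h replicates 3, 4 and 5, 30, 42 and 81 without vehicle 24 h replicates 2, 3 and 5, 22 and 63 without C1 5 h replicates 2 and 4, and 644, 13, 920, 3 and 4 without C1 24 h replicates 1 to 5. From 96 to 168 h, 31 genes changed (21 and 10, 14 with the series term), among them Coa8, a mitochondrial factor of cytochrome oxidase assembly (0.82 ± 0.16), and Ankrd11 (-1.70 ± 0.39, -0.37 with the series term). Their calls were lost in 2 and 15 of 20 fits without 1 array (highest adjusted p = 0.0602 and 0.105). This count was 18, 2 and 10 without vehicle 96 h replicates 2, 4 and 5, 281, 3, 6, 2 and 0 without vehicle 168 h replicates 1 to 5 (1241 under an unadjusted p of 0.05 in limma for the last), 5, 6, 5, 8 and 112 without C1 96 h replicates 1 to 5, and 7, 15, 54, 51 and 5 without C1 168 h replicates 1 to 5.

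In the stomach 58 genes changed from 5 to 24 h (54 higher, 4 lower), among them Mlf1 (2.70 ± 0.33), Cenpt of the kinetochore (2.21 ± 0.25), Wif1, a Wnt inhibitor (-2.11 ± 0.29), and Cyp1a1 (-3.23 ± 0.68). The call of Cyp1a1 was lost in 12 of 20 fits without 1 array (highest adjusted p = 0.0918). Mitosis genes had a median of 1.55 in this step with 2 higher, 35 when adjusted over the list alone, and DNA replication genes 0.78 with 6 higher, 23 when adjusted over the list alone. The count was 35, 34 and 33 without vehicle 5 h replicates 1, 3 and 5, 35, 27 and 27 without C1 5 h replicates 1, 2 and 4, 28, 33, 33 and 109 without vehicle 24 h replicates 2 to 5, and 36, 226, 23 and 30 without C1 24 h replicates 2 to 5.

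Among vehicle bladders alone, 1066 genes varied over the 5 times (limma's F-test), 552 with the series term and 323 without the 168 h group. Wnt6 was at 7.65 ± 0.28 (SD, n = 5) at 5 h, above the floor on 4 arrays, and at 9.35 ± 0.19 (SD, n = 5) at 168 h, with the largest F (36.4). Rasa1, a GTPase activating protein, was at 10.74 ± 0.08 (SD, n = 5) at 96 h and at 11.44 ± 0.27 (SD, n = 5) at 168 h, where 4 of the 5 arrays belong to series 2, and its F of 30.0 had an adjusted p of 0.529 with the series term.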

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

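The tests of explanations in this part were chosen after the results had been seen; the other splits of the samples were planned.

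A sample stood apart in 14 of 182 groups and measures (7.69%), where Dixon's test picks about 1 in 20 groups by chance. In mean correlation with the other arrays these were bladder vehicle 5 h replicate 3 (0.937, the others 0.959 to 0.962), vehicle 48 h replicate 1 (0.954, others 0.963 to 0.964) and vehicle 96 h replicate 4 (0.964, others 0.966). In the actin 3'/5' ratio it was bladder vehicle 96 h replicate 3 (0.79, others 0.34 to 0.44). In glandular markers it was stomach vehicle 5 h replicate 3 (10.68, others 4.82 to 5.92), counted in 2 measures of the same genes. In mean log2 levels of lists, the bladder arrays were vehicle 5 h replicate 3 for EGFR ligands and feedback (9.02, others 9.24 to 9.31), C1 5 h replicate 5 for smooth muscle (12.94, others 13.14 to 13.21) and C1 24 h replicate 1 for basal epithelial genes (10.52, others 10.96 to 11.12). Further bladder arrays were vehicle 24 h replicate 1 for epithelial junctions (11.57, others 11.38 to 11.43), vehicle 48 h replicate 5 for mitosis (8.34, others 7.55 to 7.67), C1 96 h replicate 1 for mast cells and eosinophils (8.68, others 9.34 to 9.50) and vehicle 168 h replicate 1 for fibroblast and matrix (11.07, others 12.1 to 12.45). That last array is the 1 vehicle array of 168 h outside series 2. In the stomach it was C1 5 h replicate 1 for epithelial junctions (10.16, others 9.76 to 9.82).

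The change under C1 differed between the tissues for 723 genes at 5 h and 368 at 24 h. Zic2, a zinc finger transcription factor, differed by 2.76, Herc1 by 2.39, Pdlim5 by 2.09, Tanc2 by 2.08 and Sdr42e1 by 1.97 at 5 h, all higher in the bladder. Tissue differences are confounded with series, and within series 2 the bladder changes of Herc1, Pdlim5, Tanc2 and Sdr42e1 at 5 h were -0.24, 0.47, -0.11 and 0.51, none called. With the series term 21 and 89 genes differed at 5 and 24 h. Lower in the bladder at 5 h were Cyp1a1 (-3.50), Sprr1b (-1.73), Gpatch4 (-1.68), the nuclear pore gene Nup210 (-1.62) and Fyb1, an adaptor of T cells (-1.62). At 24 h Rnase1l2 (3.41), Tanc2 (2.22), the transporter Slc4a11 (2.05), Rhpn2 (1.97) and Herc1 (1.93) were higher, and Sprr1b (-4.08), the squamous keratin Krt4 (-2.67), Birc5 and Bub1b (-2.40 each, not called with a floor of 1) and Plk1 (-2.32) lower in the bladder. Of these, the calls of Cyp1a1, Sprr1b, Nup210 and Fyb1 at 5 h were lost in 5, 10, 7 and 7 of 10 fits without 1 rat, and those of Rnase1l2, Slc4a11, Rhpn2 and Krt4 at 24 h in 4, 8, 4 and 7.

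The change under C1 differed between bladder times for 3951 genes, and between neighbouring times for 146, 192, 96 and 31 in order of time, and for 58 between the stomach times. From 5 to 24 h Grem1, an antagonist of bone morphogenetic proteins, was at 2.11, Cst6, a cysteine protease inhibitor, at 2.10, Ccne1 at 1.86, Olig1 at -2.45, Hapln4 at -2.04 and Trpm1 at -1.64. From 24 to 48 h Kif20a was at 3.46, Pttg1 at 3.17, Cdkn3 at 3.11, Rnase1l2 at -4.00, Maff at -2.04 and Grem1 at -1.81. From 48 to 96 h Tnfaip8l2 was at 1.76, P2ry12 at 1.46, Fcer1a at 1.36, Adgrf4 at -1.91, Cdca8 at -1.87 (1.31 with a floor of 1) and Birc5 at -1.79. From 96 to 168 h Rbm19 was at 1.04, Coa8 at 0.82, Ttc22 at 0.75, Ankrd11 at -1.70, Iqgap2 at -1.16 and Rbm27 at -0.77. In the stomach Mt3 was at 2.72, Mlf1 at 2.70, Cenpt at 2.21, Cyp1a1 at -3.23, Wif1 at -2.11 and Wdr25 at -0.92. Without 1 array, the calls of Grem1, Cst6, Ccne1, Olig1, Hapln4 and Trpm1 from 5 to 24 h were lost in 7, 10, 7, 12, 8 and 4 of 20 fits, and that of Grem1 from 24 to 48 h in 16 of 19. Those of Fcer1a, Adgrf4, Cdca8 and Birc5 were lost in 15, 14, 5 and 4 of 19, those of Rbm19, Coa8, Ttc22, Ankrd11, Iqgap2 and Rbm27 in 14, 2, 14, 15, 8 and 13 of 20, and those of Mt3, Cyp1a1 and Wdr25 in the stomach in 13, 12 and 14 of 20.

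Probe sets with no single named gene, which no comparison used, were called too, 1431, 1352, 1500, 716 and 1233 of 5278 in the bladder at the 5 times, and 9 and 231 of 5473 in the stomach.

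Other splits of the samples into groups of the same sizes were fitted 100 times per result, the real split included. The real count was the highest, so 1 split reached it, for the bladder at 5 h (3024, the highest other split 792), 24 h (3422, 1975), 48 h (3328, 2323) and 96 h (1897, 371). The same held for the stomach at 5 h (184, 7), the tissue differences (723, 1 and 368, 26), change over time (3951, 1341), the stomach step (58, 37) and vehicle over time (1066, 51). At 168 h in the bladder 3 splits reached 4029 (4428 at most), and at 24 h in the stomach 2 reached 2023 (2176 at most). For the bladder steps, 3 splits reached 146 (1362 at most), 4 reached 192 (991), 9 reached 96 (1655) and 8 reached 31 (3650). Chance cannot be excluded for the last 2 steps. What the splits that call several times the real count have in common was not tested.

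The first pattern weighed is the number of genes called at 5 h in the bladder. If the 2 hybridization series were its cause, the changes would shrink within series 2. The median share kept was 0.34 (quartiles 0.07 to 0.65), against 0.78, 0.74 and 0.72 at 24, 48 and 96 h. Vehicle arrays of those times are in series 1 too, and 96 h had 1897 calls, so the series alone hardly accounts for the 3024. Poorer vehicle RNA at 5 h and a change of vehicle rats up to 168 h could not be told apart. With the actin covariate the median share kept was 0.53. The part that was called within series 2 holds Spry1, Spry2, Spry4, Etv4 and Myc, for which a biological response to C1 remains open.

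The second pattern is the fall of smooth muscle genes at 168 h. The series, as inferred, is excluded as the whole cause, since the list was at -0.95 within series 2. Endothelial genes (median 0.01, quartiles -0.29 to 0.22) lay 0.89 above the smooth muscle genes (quartiles -1.15 to -0.58). This argues against a larger share of epithelium only if it lowers all stromal types alike, which was not tested, so it stays open. Fibroblast (-0.36) and neuron and glia genes (-0.66, quartiles -1.33 to 0.12) were lower too, and adipocyte genes were at 0.06. C1 replicates 5, 1 and 2 (10.76, 11.81, 12.62) lay below all vehicle arrays (13 to 13.39), 3 and 4 (13.1, 13.12) among them. Median arrays differed by -0.50 and means by -0.89 (two-sided exact p = 0.0714). Without 5 and 1 the list was still at -0.19, so these 2 carry most of the fall. A loss of muscle RNA in some rats and dissection with less muscle wall remain open and were not tested.

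The third pattern is the rise of Gkn2 and Gkn1 in the bladder. RNA of glandular stomach in the C1 samples is excluded, since Atp4b, Pgc and Tff1, which are of similar brightness in glandular stomach, had a median change of 0 (0, 0 and -0.03). The series, as inferred, is excluded too, since the share of the change of Gkn2 at 48 h kept within series 2 was 1.01. Expression by bladder cells under C1 remains open and was not tested.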

How the results depend on the processing

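The tests in this part that were chosen after the values had been seen are the floors of 1 and of the 5th percentile, the offset, the series term, the same-series control, the actin ratio, the glandular settings, the 2 arrays of lowest correlation and the 168 h groups left out, and fry. The others were planned, and the values as deposited were the first choice before their scale was seen. For the named genes, 6321 of 7154 values under another setting kept their direction and their side of the threshold, 766 were weaker, 45 stronger and 22 reversed. Leaving out 1 replicate, 4257 of 4518 values of named genes kept both, 257 were weaker, 4 stronger and 0 reversed. Of 401 values with the series term 187 kept both, and of 347 with the same-series control 253 did. For the lists 384 of 523 values kept both, 126 were weaker and 13 reversed. Of 292 counts 178 stayed within 1.5 times the reported value. Where a count or direction changed below, the cause was not tested, except that stricter thresholds call fewer genes by construction.

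Leaving out 1 replicate at a time (leave-one-out), the counts in the bladder ran from 2372 to 3039 at 5 h (3024 with all arrays), 2517 to 3902 at 24 h (3422), 2462 to 3210 at 48 h (3328), 1161 to 2082 at 96 h (1897) and 2751 to 4610 at 168 h (4029). In the stomach they ran from 77 to 154 at 5 h (184) and 1386 to 2482 at 24 h (2023). For the difference between the tissues they ran from 387 to 573 at 5 h (723) and 212 to 438 at 24 h (368). Change over time in the bladder ran from 3425 to 4690 (3951) and vehicle over time from 756 to 1282 (1066). The bladder steps ran from 3 to 920 for 24 minus 5 h (146), 131 to 337 for 48 minus 24 h (192), 38 to 127 for 96 minus 48 h (96) and 0 to 281 for 168 minus 96 h (31), and the stomach step from 23 to 226 (58).

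Thresholds. At an adjusted p under 0.01 the bladder counts were 1699 at 5 h, 2035 at 24 h, 1956 at 48 h, 812 at 96 h and 2578 at 168 h, and the stomach counts 47 at 5 h and 1009 at 24 h. The tissue differences fell to 232 at 5 h and 135 at 24 h, change over time to 1960 and vehicle over time to 392. The bladder steps were 0 for 24 minus 5 h and 0 for 168 minus 96 h (2113 and 1498 genes under an unadjusted p of 0.05 in limma), 90 for 48 minus 24 h and 34 for 96 minus 48 h, and the stomach step 10. At an adjusted p under 0.05 and a fold of at least 1.5, the bladder counts were 734, 990, 1138, 607 and 1478 in order of time, the stomach counts 94 and 869, the tissue difference at 5 h 419, and the bladder step 168 minus 96 h 12.

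Scaling. With the values as deposited and no scaling, the counts were 1129, 1041, 695 and 2434 in the bladder at 24, 48, 96 and 168 h, 87 and 926 in the stomach, 1218 and 78 for the tissue differences at 5 and 24 h, and 213 for vehicle over time. The bladder steps were 229 for 24 minus 5 h, 72 for 48 minus 24 h, 24 for 96 minus 48 h and 0 for 168 minus 96 h (458 under an unadjusted p of 0.05 in limma), and the stomach step 9. In the bladder at 5 h, the lists of fibroblast and matrix (-0.11), ribosome biogenesis and MYC targets (-0.13) and smooth muscle (-0.11) and the gene Nop16 (-0.11) reversed. With each array centred on its median, the bladder steps were 36 for 24 minus 5 h, 126 for 48 minus 24 h and 11 for 168 minus 96 h, the stomach step 130, and the proteasome list in the bladder at 48 h reversed (-0.01).

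Floor and offset. With the floor at the 5th percentile, the steps 168 minus 96 h and 96 minus 48 h had 20 and 10 genes and the stomach step 17. With a floor of 1, the steps 48 minus 24 h and 96 minus 48 h had 117 and 9 and the stomach step 15. The tissue difference of Bub1b at 24 h (0.59) and the step of Cdca8 from 48 to 96 h (1.31) then reversed. With a pseudocount of 16, the steps 168 minus 96 h and 96 minus 48 h had 16 and 9 and the stomach step 17. With an offset that makes all values positive, the tissue differences were 1156 at 5 h and 689 at 24 h and the stomach step 199. Signal over background sets the limit here, since a gene at the floor on all arrays of a group has no measured level there and its change is a lower bound.

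Probe sets and dim genes. With every probe set on its own, the counts were 5086 in the bladder at 5 h, 1805 and 695 for the tissue differences at 5 and 24 h, 2359 for vehicle over time, 273 for the step 24 minus 5 h and 192 for 96 minus 48 h. With the mean of a gene's probe sets, the steps 24 minus 5 h and 168 minus 96 h were 220 and 13, and Dst in the bladder at 24 h reversed (0.02). With the dim 40% left out, the bladder counts were 1962 at 5 h and 2197 at 48 h, and the tissue differences 422 at 5 h and 171 at 24 h. The steps were 55 for 24 minus 5 h, 47 for 48 minus 24 h and 9 for 96 minus 48 h, and 13 in the stomach.

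Model. With array quality weights, the bladder counts were 5845 at 24 h, 5050 at 48 h and 3236 at 96 h, the stomach counts 772 and 3337, the tissue differences 1402 and 1234, change over time 6212 and vehicle over time 2502. The bladder steps were 2746, 1561, 733 and 269 in order of time, and the stomach step 455. With only the groups of the comparison in the fit, the counts were 1249 in the bladder at 168 h, 426 and 942 in the stomach, 182 for the tissue difference at 24 h, and 11 and 1 for the bladder steps 24 minus 5 h and 168 minus 96 h. With the animal as replicate block, the tissue difference was 971 at 5 h and 561 at 24 h, and with bladder minus stomach taken per animal 857 and 407. The correlation of the changes of the 2 arrays of a rat had a median of 0.14 over 20 rats, and the consensus correlation was 0.11. With the inter-gene correlation estimated, 0 of 312 gene list tests passed (27 under an unadjusted p of 0.05 in camera), against 61 with the preset correlation and 68 with fry.

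Series. With hybridization series as a term, which rests on vehicle 168 h replicate 1 alone, the counts were 59, 434, 1542 and 1220 in the bladder at 5, 24, 48 and 96 h, 21 and 89 for the tissue differences, 2049 for change over time, 552 for vehicle over time and 14 for the step 168 minus 96 h. Erbb2 (0.59) and Loxl2 (-1.13) in the bladder at 5 h and Herc1 at 24 h, in the bladder (-0.09) and in the tissue difference (-0.02), reversed. Rab32 reversed in the bladder at 5 h (-0.93), 24 h (-0.90), 48 h (-0.63) and 96 h (-0.83). The fibroblast and matrix (-0.91) and smooth muscle (-0.04) lists at 5 h, the wound and matrix remodelling list at 48 h (-0.01) and the macrophage list at 96 h (-0.71) reversed. For fibroblast and matrix that array stood apart from its group, so its own deviation enters the value. With the same-series vehicle at 168 h as control, the count at 5 h was 858. Herc1 (-0.24), Pals2 (-0.13), Tanc2 (-0.11) and Wac (-0.03) at 5 h, Ahsa1 (-0.02), Ankrd11 (-0.22) and Herc1 (-0.51) at 24 h, Cntfr at 48 h (0.09) and Adamts10 at 96 h (0.03) reversed, as did the smooth muscle list at 5 h (-0.04).

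Arrays and covariates. Without the 168 h groups, vehicle over time was 323. Without the 2 bladder arrays of lowest correlation, the count at 168 h was 1118, and the steps 24 minus 5 h and 168 minus 96 h were 340 and 8. With the actin 3'/5' ratio as covariate, the count at 5 h was 254, the tissue difference at 5 h 57, change over time 1391 and the step 24 minus 5 h 0 (1513 under an unadjusted p of 0.05 in limma). The lists of fibroblast and matrix (-0.52) and smooth muscle (-0.11) and the gene Loxl2 (-0.29) at 5 h then reversed. Without the arrays high in glandular markers, the stomach count at 5 h was 117 and the stomach step 22, and the squamous differentiation list at 24 h reversed (-0.01). With the glandular mean as covariate, the stomach step was 108 and the glandular stomach list at 5 h reversed (-0.01).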

Other observations

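The tests of hypotheses in this part were chosen after the results had been seen. One hypothesis is that division began earlier in the stomach than in the bladder. It needs the bladder to reach its rise in mitosis genes after 24 h, and the median step from 24 to 48 h was 2.03, with 29 of 36 genes called higher and all 36 higher, whereas the difference from the stomach at 24 h was -1.25. The bladder floor (7.20, against 4.82 in the stomach) can hide part of a bladder rise at 24 h, so that difference decides little, and Bub1b was at 0.59 in it with a floor of 1. The step is consistent with an earlier wave in the stomach, where 48 h was not sampled.

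Another hypothesis is that the cholesterol synthesis genes called higher in the bladder at 24 h rise in the stomach of the same rats. Of the 13 genes, 3 were called higher in the stomach at 24 h. All 13 were higher there (median 0.49), so the set goes with the hypothesis. For single genes, a missed threshold excludes nothing.

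For the rise of mast cell and eosinophil genes at 96 h (median 1.14), more immune cells of every kind could not be excluded. The median was lowest for T and NK cells, at 0.08, and 0.52 for macrophages and 0.41 for MHC class II genes, so the rise of mast cell genes may be part of a wider one.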
